A study of Mus musculus with 5 samples.

How the data were processed

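Single-cell RNA sequencing was carried out on cells from the proximal femur and distal tibia of mice at postnatal day 7.5. The mice carried Col10a1-Cre, in which the promoter of the collagen X gene of hypertrophic cartilage drives Cre recombinase, and ROSA-ZsGreen, a green fluorescent reporter at the Rosa26 locus that Cre switches on for good and that daughter cells inherit. Per the labels' protocols, bone and hypertrophic cartilage were cut up and digested with collagenase, and dead cells were removed with a kit. Cells of the unsorted group were depleted of blood and endothelial cells with magnetic beads against CD31, CD45 and Ter119, and cells of the sorted group were ZsGreen-positive cells collected by flow cytometry. Libraries were made with the 10x Genomics 3′ kit, which counts each captured RNA molecule once by a unique molecular identifier (UMI) near the 3′ end of the transcript. The labels name 4 unsorted samples and 1 sorted sample. They do not say whether the samples came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

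The deposited values were raw UMI counts per gene and barcode, not normalized, for 28000 features including Cre and ZsGreen and for 6794880 barcodes, most of which held no cell. Per the file headers, the counts were made with Cell Ranger version 3.0.2 for the unsorted libraries and 3.1.0 for the sorted one. The submitters' processing notes name Cell Ranger 2.1.1 and genome build mm10, so the version given there differs from the headers. The sort, the library and the software version were the same split of the samples, so these cannot be told apart. The matrices of unsorted replicates 1 and 2 were identical in every value and were counted as 1 library, called unsorted replicate 1 from here on. Unsorted replicates 3 and 4 were more alike than either was to replicate 1. Over all cells the chi-square per degree of freedom was 11.9 between replicates 3 and 4, 478 between 1 and 3, and 525 between 1 and 4. Replicates 3 and 4 shared 0 of their 1000 barcodes with the most UMIs and differed beyond counting noise, so they were kept as separate libraries. Neither check can tell separate animals from the same cell suspension loaded again. That left 3 distinct unsorted libraries and 1 sorted library.

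Total counts were 88007151 UMIs in unsorted replicate 1, 191323906 in replicate 3, 208437983 in replicate 4 and 49311705 in the sorted library. Barcodes were kept as cells with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs on mitochondrial genes. The mitochondrial limit removed 65.8%, 44.3% and 44.9% of the barcodes with at least 1000 UMIs in unsorted replicates 1, 3 and 4 and 20.3% in the sorted library. Among the cells kept, median mitochondrial percents were 4.67, 4.88, 4.92 and 3.25 in osteoblast-like, 5.87, 5.96, 6.14 and 3.48 in marrow stromal-like and 5.32, 5.16, 5.36 and 3.61 in hypertrophic chondrocyte-like cells, the sorted library last. Doublets were called within each library by the Scrublet implementation in scanpy and removed: 26, 171, 226 and 6 barcodes in the same order. This left 2581, 5818, 5768 and 1074 cells. Counts were scaled to 10000 per cell and log-transformed for clustering only. The cells of all distinct libraries were clustered together by the Leiden method at resolution 1.0 on 30 principal components of 2000 variable genes with 15 neighbours. Y-linked genes and Xist were left out of the variable genes.

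Clusters were named only from fixed marker lists. A name needed at least 3 markers of the type with a log2 fold above 1 over the median of the clusters, with 10 CPM added to both sides. A type that alone had the most markers among the cluster's top 10 genes, at least 3, took the name. Otherwise the type with the highest mean fold took it, if no other type had more markers among those 10 genes. Cluster 12 held 12 osteoblast markers above that fold and cluster 14 held 13 chondrocyte markers, and both failed this last condition. A cluster whose median UMIs lay more than 3-fold below its samples' also needed 3 markers among its top 10 genes, a rule tightened after the clusters were seen and before any gene test. Clusters without a name are called by number. They held 8.64%, 24.3% and 19.6% of the cells of unsorted replicates 1, 3 and 4 and 21.8% of the sorted cells. The class names are rebuilt from these markers and are not the authors' own annotation.

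UMI counts were summed per library over all cells, and per library and class for classes with at least 30 cells in a library. Sums were tested with edgeR's quasi-likelihood test, with TMM scaling, the filterByExpr filter on low counts and robust dispersion, and Benjamini-Hochberg adjustment at 0.05. With 1 sorted library the residual spread came from the unsorted libraries alone, and the sorted library was assumed to vary like them. Classes were compared within libraries with the library as a block. Differences between classes in the sorted-unsorted effect were tested as interaction terms. Fixed lists of genes, 22 of cell type markers and 19 of pathways, were tested with camera on log2 CPM. It was run with a preset correlation of 0.01 and again with an estimated correlation. The estimated form has only the few residual degrees of freedom of these libraries, so it could hardly pass for any list. Members were also counted after adjustment over all genes and adjusted over the list alone. A list needed 3 tested members. CPM is the UMI count of a gene divided by the total of the library or class, in the usual unit.

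Named genes were the 12 genes with the largest log2 change in each direction among those with an adjusted p below 0.05, at least 20 CPM in the higher group and the sorted library beyond every unsorted one, or, between classes, the same direction in every library. Gene models without names and mitochondrial genes were left out, and between classes only members of the pathway lists outside the class markers were eligible. Where fewer passed, the same ranking without the threshold gave values only. Col10a1, Cre, ZsGreen and members of the lists were also named. The design, the gene lists, this rule and the alternatives were fixed before the data were examined. Gene positions come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes.

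Shares of cells have exact binomial intervals at the 95% level. A count of 0 allows up to 3 counts. Both cover counting error only. Shares of cells with a reporter UMI were also computed after each cell was thinned to 10000 UMIs, with shallower cells left out. Free RNA was estimated from barcodes ranked 15000 to 50000 by UMIs, which hold no cells, as the level those droplets would add to a cell. The edgeR script was tested on simulated counts for the real genes and libraries, with 200 genes changed by 2-fold or 4-fold. It recovered 99% of the 2-fold changes in osteoblast-like cells, 57% in hypertrophic chondrocyte-like, 60% in marrow stromal-like and 60% in osteoprogenitor-like cells. Over all cells it recovered 3% of the 2-fold and 45% of the 4-fold changes. Simulated data without changes gave 0 calls in each of these comparisons. The changed genes were drawn from those with at least 20 CPM. All libraries were drawn with the same spread, so the simulation could not check whether the sorted library varies like the unsorted ones. Each gene had the spread typical of its level, and libraries were drawn independently, without the likeness of replicates 3 and 4. The recovery and the 0 calls hold only under that setting, and the real data may give less recovery and more false calls.

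Alternatives were DESeq2 in place of edgeR, RLE factors, no low-count filter, each library left out, a minimum of 2000 UMIs, mitochondrial limits of 5% and 20%, doublets kept, clustering at resolution 0.5 and 2.0 and of each library alone, cells thinned to 2000 UMIs, blood cell classes left out, and the identical libraries counted as separate. Single osteoblast-like clusters, cells of 20000 to 40000 UMIs only, library size in place of TMM factors and the class comparisons without the sorted library were added after the data were seen. Matching unsorted to sorted osteoblast-like cells by nearest UMIs left a gap in depth, and the range of 20000 to 40000 UMIs replaced it before its fit was run. Not analysed here were the raw reads and unspliced transcripts. The design asked for at least 2 distinct libraries on each side of a test between unsorted samples by label, and 1 side held 1, so none was made.

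The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.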

Results

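Single cells from the proximal femur and distal tibia of mice at postnatal day 7.5 were profiled by droplet sequencing. In these mice, cells that have expressed collagen X, and the cells that descend from them, carry the green reporter ZsGreen. Unsorted cells, which were depleted of blood and endothelial cells, showed which cell types were captured, and cells sorted for ZsGreen showed which of them carried the label. Replicates 1 and 2 of the 4 unsorted samples held identical values and count as 1 library. The 3 distinct unsorted libraries held 88007151 UMIs (replicate 1), 191323906 (replicate 3) and 208437983 (replicate 4), and the sorted library 49311705. They gave 2581, 5818, 5768 and 1074 cells, with medians of 18753, 21317, 23899.5 and 32806.5 UMIs per cell in the same order. The sorted side was a single library throughout, so its own spread was not measured. Values below are given for unsorted replicates 1, 3 and 4 and then the sorted library unless stated otherwise.

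Col10a1 encodes collagen X, the collagen of hypertrophic cartilage (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085 on GRCm38). In hypertrophic chondrocyte-like cells it stood at 35300, 33500 and 35600 CPM in the unsorted libraries and 37500 CPM in the sorted one. Cre, which the Col10a1 promoter drives, was found in the same cells at 182, 209, 224 and 249 CPM, with a UMI in 57.5%, 56.4%, 51.8% and 62.3% of them. Neither differed between the sorted library and the unsorted ones by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The adjusted p was 0.954 for Col10a1 (log2 0.18, SE 0.312) and 0.856 for Cre (log2 0.33). These cells were not all of those with Col10a1. Cluster 3, of fewer UMIs per cell (medians 5698.5, 2938, 3267 and 15052) and without a name, held 22, 94, 91 and 21 cells with Col10a1 at 97600, 58900, 65000 and 84100 CPM and a ZsGreen UMI in 13.6%, 19.1%, 15.4% and 42.9%. Cre UMIs were found in 18.2%, 11.7%, 15.4% and 9.52% of them. Cluster 14, also without a name and with Ihh as its first marker, held 27, 271 and 292 unsorted cells and 0 of 1074 sorted ones. Its Col10a1 stood at 6070, 3180 and 2700 CPM, with a UMI of it in 92.6%, 95.9% and 96.9% of the cells, of Cre in 3.70%, 4.43% and 2.74% and of ZsGreen in 3.70%, 1.48% and 3.77%. In osteoblast-like cells Cre was all but absent, at 0.178, 0.264 and 0.114 CPM in the unsorted libraries and in 0 of 397 sorted cells. Marrow stromal-like cells held no Cre UMI in any unsorted library and 0.230 CPM in the sorted one. Over all cells of a library, Cre stood at 6.79, 8.54, 7.60 and 28.4 CPM and ZsGreen at 5.41, 3.53, 4.10 and 18.4 CPM. The X-linked Xist lay between 293 and 338 CPM and the Y-linked Ddx3y between 25.8 and 45.5 CPM in every library, so each library held cells of both sexes.

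Skeletal cells made up most of the sorted library. Osteoblast-like cells, which express the type I collagen gene Col1a1 and the osteocalcin gene Bglap, were 37.0% of the sorted cells (397 cells, exact 95% interval 34.1% to 39.9%) and 18.2% ± 2.42 (SD, n = 3) of the unsorted ones. Marrow stromal-like cells, which express Cxcl12, Adipoq and Kitl, factors of the blood-forming niche, were 14.8% of the sorted cells (159 cells, 12.7% to 17.1%) and 1.72% ± 0.252 of the unsorted ones, an 8.60-fold difference. Hypertrophic chondrocyte-like cells were 14.1% (151 cells, 12% to 16.3%) against 2.34% ± 0.706, a 6.03-fold difference. Osteoprogenitor-like cells, marked by Postn and Aspn, genes of the periosteum and other fibrous tissue, were 8.01% (86 cells, 6.45% to 9.79%) against 4.86% ± 1.86. Osteocyte-like cells were 2.33% (25 cells, 1.51% to 3.42%) against 0.536% ± 0.0423.

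Chondrocyte-like, B cell-like and erythroid-like cells were rare or missing after the sort. Chondrocyte-like cells, which make up the growth plate ahead of hypertrophy, were 3.02%, 22.3% and 26.2% of the unsorted libraries and 0 of 1074 sorted cells, which allows a share of up to 0.279%. B cell-like cells were 11.8%, 1.87% and 2.03% of the unsorted libraries and 0 of the sorted cells. Erythroid-like cells were 20.8% ± 6.20 (SD, n = 3) of the unsorted cells and 0.652% of the sorted ones (7 cells). Mural-like cells of the vessel wall were at 0.745% (8 cells) against a mean of 0.439%. Cluster 24, which took no name, was at 1.02% (11 cells) against 0.355%. Both rest on few cells. The highest unsorted shares were 0.572% and 0.581%, so neither difference stands clear of counting error. The share of each of these groups in the sorted library lay outside the range of the 3 unsorted libraries. A comparison of 1 library with 3 cannot give an exact permutation p below 0.25, so no test of shares was made. Shares depended on the clustering. The osteoprogenitor-like share was 20.5% at resolution 0.5 and 5.59% at 2.0, and the osteocyte-like share 8.01% with each library clustered alone. The hypertrophic chondrocyte-like share was 5.31% at resolution 2.0, and no cluster took that name at resolution 0.5 or with each library clustered alone. The sort and the magnetic depletion of blood and endothelial cells both set these shares, so they are not shares of the intact tissue.

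**Figure D1:**
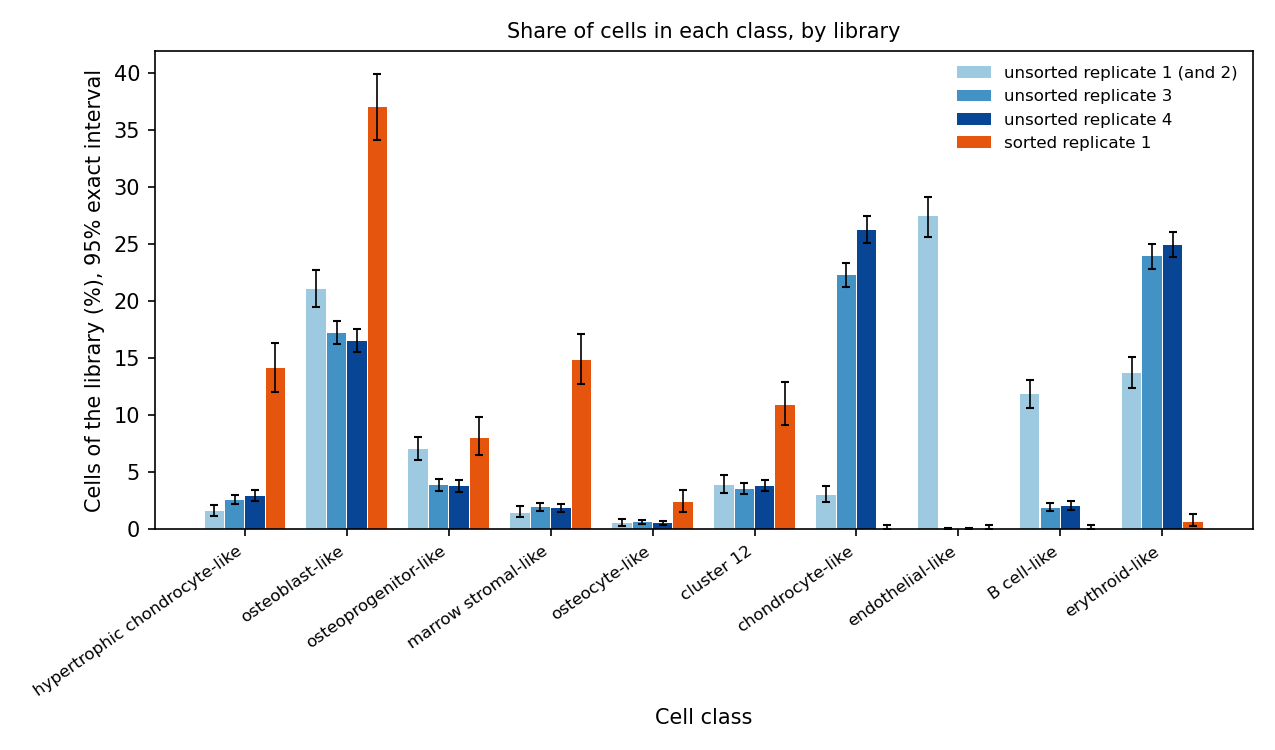
Bars give the percent of each library's cells in each class, by library (3 unsorted and 1 sorted), with exact 95% intervals. Hypertrophic chondrocyte-like cells were 14.1% and marrow stromal-like cells 14.8% of the sorted library, against means of 2.34% and 1.72% in the unsorted ones.

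ZsGreen transcripts were also found in osteoblast-like, osteoprogenitor-like and marrow stromal-like cells. A ZsGreen UMI was seen in 62.5%, 37.6% and 42.3% of the unsorted and 64.2% of the sorted hypertrophic chondrocyte-like cells. In osteoblast-like cells the shares were 14.9%, 15.2%, 18.8% and 39.0%, in osteoprogenitor-like cells 14.4%, 11.6%, 12.1% and 25.6%, and in marrow stromal-like cells 5.41%, 6.36%, 12.3% and 35.2%. Free RNA would give at most 0.0425, 0.0687 and 0.0994 CPM of ZsGreen in these 3 classes, where the lowest levels were 6.78, 8.43 and 3.58 CPM. Unsorted cells of other classes held it too, in 3.85%, 1.24% and 1.06% of chondrocyte-like cells (median UMIs 38631, 31862 and 32793) and 2.55%, 0.792% and 0.975% of erythroid-like cells (36756, 21975 and 23728). It was 5.52% in endothelial-like cells of replicate 1, which the 2 UMIs in 37 marrow stromal-like cells of that library did not exceed, and 7.69% in neutrophil-like cells of replicate 4 (3 of 39 cells, exact 95% interval 1.62% to 20.9%). Osteoblast-like cells had medians of 29851, 24016, 24807.5 and 45332 UMIs and marrow stromal-like cells of 14144, 10384.5, 10922 and 20300. The sorted cells were thus read more deeply, and each cell was also thinned to 10000 UMIs. The shares were then 22.2%, 17.9%, 27.9% and 32.4% for hypertrophic chondrocyte-like, 6.86%, 7.36%, 8.45% and 12.7% for osteoblast-like, 6.83%, 5.03%, 10.1% and 10.4% for osteoprogenitor-like and 7.69%, 4.84%, 12.5% and 22.4% for marrow stromal-like cells. The level of ZsGreen rose in marrow stromal-like cells of the sorted library, from 3.58, 5.61 and 15.4 to 23.7 CPM (log2 1.48, SE 0.403, adjusted p = 0.0454 by edgeR), a call lost without unsorted replicate 3 (adjusted p = 0.250) and with library size in place of TMM factors (adjusted p = 0.0888). It did not pass the threshold in osteoblast-like (log2 0.65, adjusted p = 0.221), osteoprogenitor-like (adjusted p = 0.0715) or hypertrophic chondrocyte-like cells (adjusted p = 0.846). Without unsorted replicate 1 it passed in all 3 (adjusted p = 0.00131, 1.83e-09 and 0.000401), and in osteoprogenitor-like cells also without replicate 3 (0.00127) or 4 (8.39e-05), but those osteoprogenitor calls are not relied on. Of the 94 ZsGreen UMIs in sorted osteoprogenitor-like cells, 64 lay in 1 cell, and without the highest cell of each library the levels were 8.17, 7.67, 9.23 and 9.82 CPM. The sort itself selected on ZsGreen, and no sorted cell can be called unlabelled from a missing UMI.

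**Figure D2:**
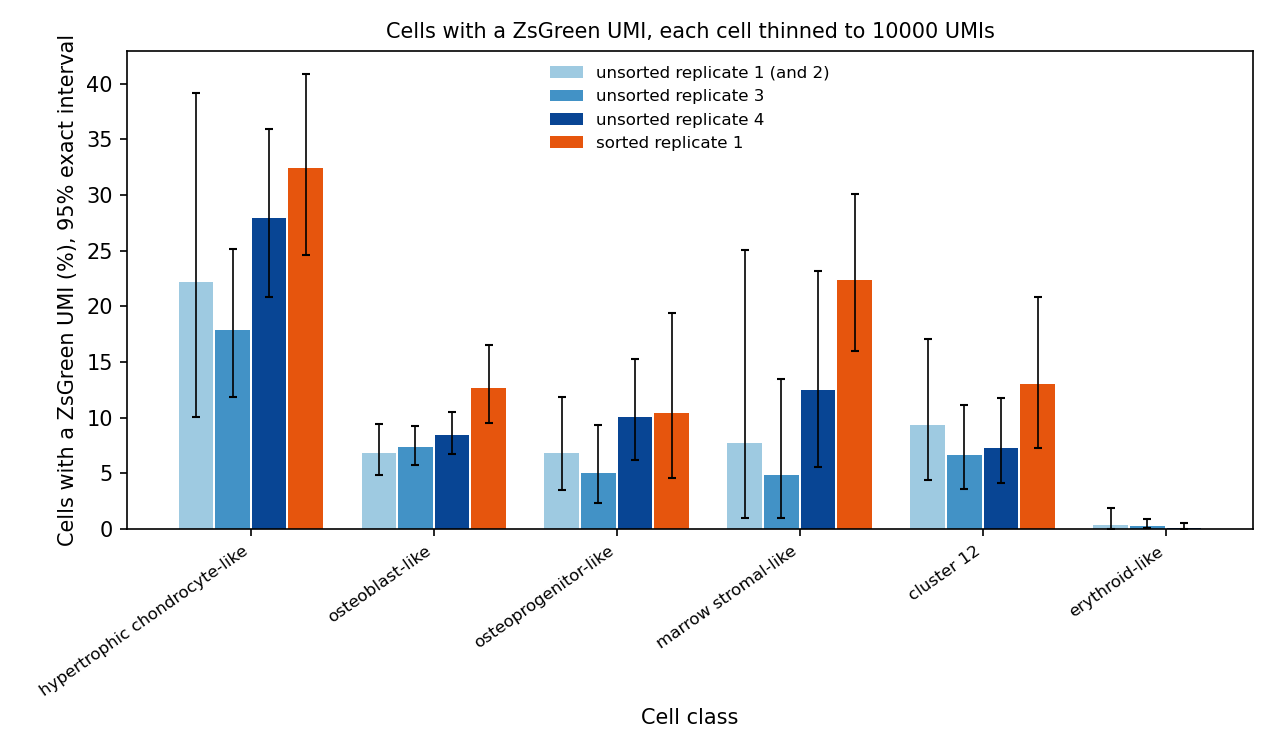
Bars give the percent of cells with at least 1 ZsGreen UMI after thinning to 10000 UMIs per cell, by class and library (3 unsorted and 1 sorted), with exact 95% intervals. Osteoblast-like cells reached 12.7% in the sorted library and at most 8.45% in the unsorted ones, and unsorted erythroid-like cells stayed at or below 0.344%.

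Over all cells, 1 gene was higher in the sorted library and 9 were lower, among them genes of blood cells. Esm1, which encodes the secreted proteoglycan endocan and marked the marrow stromal-like cluster (ENSMUSG00000042379, chromosome 13), rose 8.11-fold, from 7.32 ± 0.925 CPM (SD, n = 3) to 59.7 CPM (log2 3.02, SE 0.110, adjusted p = 0.0451). Ikzf1, which encodes the lymphoid factor Ikaros, went from 33.4 ± 7.01 to 0.401 CPM (log2 -6.37), and Ank1, which encodes the ankyrin of the red cell membrane, from 22.5 to 0.920 CPM (log2 -4.62). Bcl11a, a repressor of fetal globin genes (log2 -4.30), Fermt3, an integrin activator of blood cells (log2 -4.85), Ces2g (log2 -6.64) and Bex4 (log2 -5.52) fell as well, each with an adjusted p of 0.0451. Values without a call were 1370 CPM against 191 ± 35.9 for the chemokine gene Cxcl12 (log2 2.84, adjusted p = 0.0602), 72.1 against 6.54 for the adiponectin gene Adipoq (log2 3.42, adjusted p = 0.0654) and 2320 against 335 ± 208 for the osteocalcin gene Bglap2 (log2 2.85, adjusted p = 0.125).

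In all, 10 of 17154 genes passed, 1 higher and 9 lower, with 3817 genes at an unadjusted p under 0.05, and DESeq2 called 2357. The count rested on which libraries were used. It was 11158 without unsorted replicate 1 (5302 higher and 5856 lower), 0 without replicate 3 (1519 unadjusted) and 0 without replicate 4 (1530 unadjusted). It was also 0 with the blood classes left out (1667 unadjusted) and with library size in place of TMM factors (3404 unadjusted). Among the fixed lists, marrow stromal markers were higher in all 12 members adjusted over the list alone (adjusted p = 1.72e-08 by camera, 0.322 with an estimated correlation). S phase genes were lower in all 20 (adjusted p = 1.96e-12, 0.322 with an estimated correlation) and genes of G2 and mitosis in 19 of 20 (adjusted p = 1.08e-10, 0.322 with an estimated correlation). None of the members of these 3 lists passed over all genes. The cell types present differ between the sorted and unsorted libraries, so these are differences of mixtures.

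Within hypertrophic chondrocyte-like cells, 1 gene differed between the sorted library and the unsorted ones. Cxcl12, which encodes the chemokine that retains blood stem cells in the marrow (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), rose 6.06-fold, from 7.49 ± 1.29 CPM (SD, n = 3) to 45.5 CPM (log2 2.60, SE 0.268, adjusted p = 0.0224 by edgeR). The same gene stood at 12000 CPM in sorted marrow stromal-like cells. Free RNA of the sorted library would add 0.847 CPM of it to hypertrophic chondrocyte-like cells. The difference was not particular to them, since Cxcl12 in osteoblast-like cells was at 7.55, 15, 15 and 46.2 CPM, without passing (log2 1.93, adjusted p = 0.0960), and marrow stromal-like cells, which it marks, were 8.60-fold more frequent in that library. Fos, an immediate-early gene, was at 1320 CPM against 591 ± 78.0 (log2 1.24, adjusted p = 0.267), and Atf3, a stress-induced gene, at 656 against 306 ± 18.1 (log2 1.16, adjusted p = 0.267). Col1a1 was at 230 CPM in the sorted cells against 925 ± 485 in the unsorted ones (log2 -1.98, adjusted p = 0.846 by edgeR). Free RNA was estimated at 0.339%, 2.02%, 1.94% and 0.138% of the UMIs of these cells. Col1a1 stood in it at 23400, 14900, 15000 and 28500 CPM, so part of the unsorted level may be free RNA.

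The test ran on 12413 genes, of which 719 had an unadjusted p under 0.05, and DESeq2 called 7. It rested on 40, 149, 168 and 151 cells, and 672 genes passed without unsorted replicate 1 (330 higher and 342 lower), 23 without replicate 3 and 12 without replicate 4. The call on Cxcl12 was lost with library size in place of TMM factors (log2 2.56, adjusted p = 0.259) and with the identical libraries counted as separate (log2 2.65, adjusted p = 0.346). With clustering at resolution 2.0 it was lost and its direction was reversed (log2 -0.34, adjusted p = 0.932, 3 libraries). Immediate-early and heat shock genes were higher in 17 of 20 members, 0 over all genes and 4 adjusted over the list alone (adjusted p = 7.25e-07, 0.696 with an estimated correlation). Osteoblast markers were lower in 4 of 12 adjusted over the list alone and in 0 over all genes (adjusted p = 0.00120 by camera, 0.696 with an estimated correlation). As for Col1a1, free RNA is not excluded for part of that fall.

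Marrow stromal-like cells of the sorted library held more transcripts of Mepe, Dmp1, Atf3, Fos and Jun, among others. Mepe, which encodes a phosphoglycoprotein of osteocytes and mineralizing matrix (ENSMUSG00000053863, chromosome 5), stood at 31.3 CPM against 0.569 ± 0.986 (SD, n = 3), where the 3 unsorted libraries together held 2 UMIs (log2 5.49, SE 0.595, adjusted p = 9.6e-08). Dmp1 lies near it on chromosome 5 and encodes a matrix protein needed for osteocyte maturation. It rose from 3.86 ± 3.35 to 46.9 CPM (log2 3.40, SE 0.394, adjusted p = 3.79e-07 by edgeR). Osteocyte-like cells were 2.33% of the sorted library and on average 0.536% of the unsorted ones. The spread of Mepe and Dmp1 over single cells was not examined, so a few osteocytes or doublets among these cells are not ruled out. Atf3 rose from 33.1 ± 6.20 to 183 CPM (log2 2.53, SE 0.228, adjusted p = 2.07e-09), and the kinase gene Pim1 from 29.7 to 136 CPM (log2 2.26, adjusted p = 2.58e-08). Fos rose from 662 to 2290 CPM (log2 1.90) and Jun from 602 to 2260 CPM (log2 2.02). The interferon-induced genes Cxcl10 (log2 2.50, adjusted p = 0.000257) and Isg15 (log2 2.03, adjusted p = 0.000124) rose too. Col11a2, which encodes a collagen of cartilage, fell from 99.8 ± 12.7 to 14.5 CPM (log2 -2.69, SE 0.280, adjusted p = 4.37e-08). Smpd3, which encodes a sphingomyelinase needed for mineralization (log2 -1.79), the matrix protease gene Mmp19 (log2 -1.97) and the clock gene Per1 (log2 -1.59) fell as well. Cxcl12 itself was at 12000 CPM against 14000 ± 710 (log2 -0.12, adjusted p = 0.786).

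Of 10107 genes, 229 passed, 137 higher and 92 lower, with 1534 at an unadjusted p under 0.05. DESeq2 called 65, of which 58 were among them. The count was 1297 without unsorted replicate 1 (745 higher and 552 lower), 142 without replicate 3 and 173 without replicate 4. Replicate 1 gave only 37 of these cells. With library size in place of TMM factors 99 genes were higher and 111 lower. At least 2000 UMIs per cell left replicate 1 out and gave 6 genes, of which 4 were shared, and the identical libraries counted as separate gave 26, all shared. Without replicate 3 the calls on Mmp19 (adjusted p = 0.0521) and on 2 other named genes, Tspan33 and Stard10, were lost, the last also with library size in place of TMM factors (adjusted p = 0.0558). Immediate-early and heat shock genes were higher in 14 of 20 over all genes and in 16 adjusted over the list alone (median log2 1.31, adjusted p = 2.07e-17, 0.610 with an estimated correlation). Osteocyte markers were higher in 2 of 4 (adjusted p = 0.00819, 0.610 with an estimated correlation). Chondrocyte markers were lower in 2 of 13 over all genes and 3 adjusted over the list alone (adjusted p = 7.84e-08, 0.610 with an estimated correlation). Together these stood at 749, 1990, 2700 and 363 CPM, of which free RNA would give 60.5, 1350, 1350 and 4.21 CPM, so part of the unsorted level lay within the estimate for free RNA.

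In osteoblast-like cells of the sorted library, Cxcl1, Emp1, Fos and Jun were among the genes that rose. Cxcl1, which encodes a chemokine that draws neutrophils (chromosome 5), rose 16.5-fold, from 1.72 ± 0.402 CPM (SD, n = 3) to 27.9 CPM (log2 4.04, SE 0.197, adjusted p = 0.000874). Emp1, which encodes an epithelial membrane protein (ENSMUSG00000030208, chromosome 6), rose 5.24-fold, from 24.9 ± 0.784 to 125 CPM (log2 2.39, SE 0.0928, adjusted p = 0.000874). Fos rose from 543 ± 122 to 2190 CPM (log2 2.08, SE 0.216, adjusted p = 0.0254) and Jun from 391 ± 30.3 to 1270 CPM (log2 1.76, SE 0.0943, adjusted p = 0.00105). Sgk1, a kinase gene induced by glucocorticoids, rose from 9.60 ± 0.119 to 43.0 CPM, and Klf6, Zfp36, Egr1, Nr4a1 and Phlda1 rose by log2 1.82, 1.82, 1.30, 1.96 and 2.00. Of the 9 genes that fell, Hist1h2al (log2 -1.89), Tpm3-rs7 (log2 -1.41), Rps12-ps3 (log2 -1.10), Rpl10-ps3 (log2 -1.06) and the ribosomal RNA-like AY036118 (log2 -2.45) are copies or pseudogenes whose reads can be shared with other loci, so these 5 falls are uncertain. The 12 osteoblast markers themselves did not move as a list (0 of 12, adjusted p = 0.988).

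In this class 102 of 13189 genes passed, 93 higher and 9 lower, with 1844 at an unadjusted p under 0.05. DESeq2 called 244, with 98 in common. The count was 2896 without unsorted replicate 1 (1622 higher and 1274 lower), 111 without replicate 3 (92 and 19) and 310 without replicate 4 (227 and 83), so the split between higher and lower depended on the libraries used, and no named gene lost its call in these 3 fits. Without the low-count filter the calls on Fos (adjusted p = 0.125) and Nr4a1 (adjusted p = 0.101) were lost, and that on Nr4a1 also with library size in place of TMM factors (adjusted p = 0.0505). Immediate-early and heat shock genes were higher in 12 of 20 over all genes and 18 adjusted over the list alone (median log2 1.46, adjusted p = 2.34e-16, 0.578 with an estimated correlation). Marrow stromal markers were higher in 0 of 12 over all genes and 4 adjusted over the list alone (adjusted p = 0.00301, 0.578 with an estimated correlation). Chondrocyte markers were lower in 0 of 13 (adjusted p = 0.00417, 0.634 with an estimated correlation). They stood at 4090, 4570, 4390 and 3290 CPM, of which free RNA would give 29.5, 578, 537 and 2.08 CPM. The class held a pair of clusters in different proportion, since cluster 11 made up 17.9%, 29.7% and 30.6% of the unsorted osteoblast-like cells and 62.7% of the sorted ones (249 of 397, 57.8% to 67.5%). Within cluster 10 alone 1 gene passed, Fos, and 1378, 11 and 2 passed without unsorted replicate 1, 3 and 4. Within cluster 11 alone 276 genes passed, and 2673 without replicate 1. The sorted cells also had more UMIs each.

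**Figure D3:**
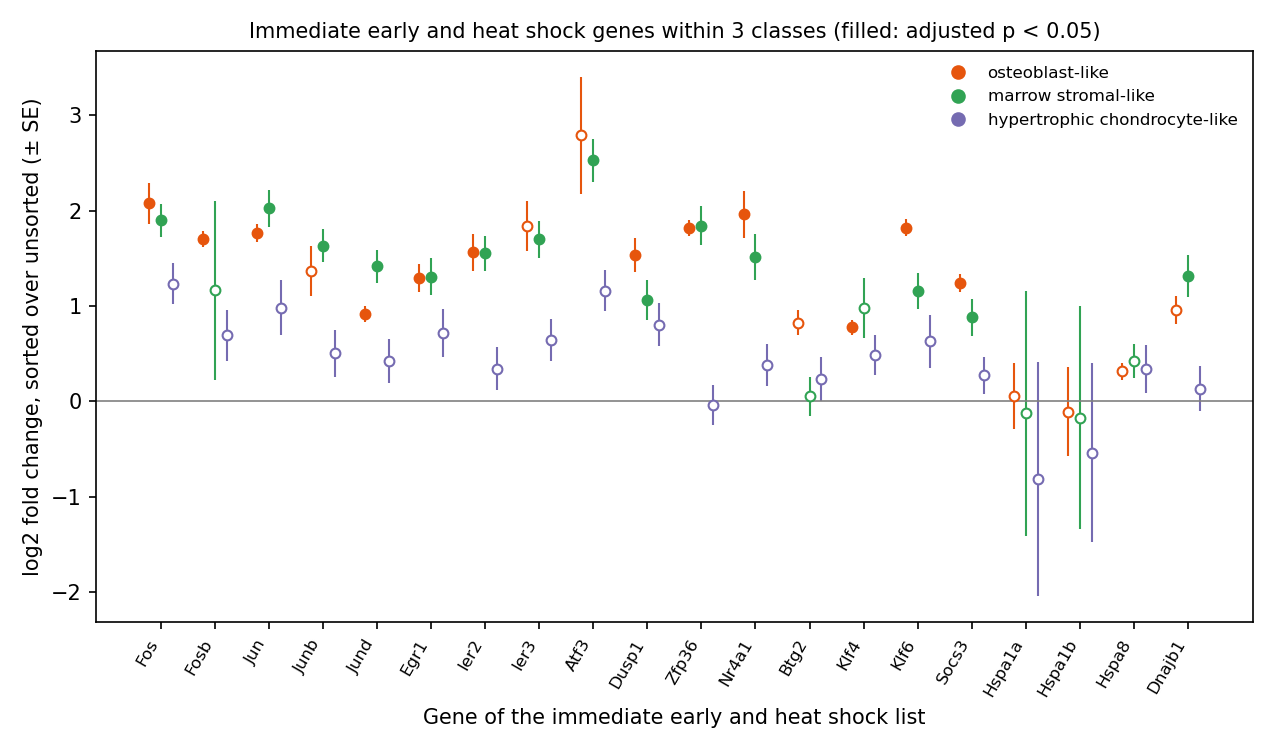
Points give the log2 difference, sorted over unsorted, with its standard error for the 20 immediate-early and heat shock genes in 3 classes, and filled points passed the test. In all, 12 points are filled in osteoblast-like, 14 in marrow stromal-like and 0 in hypertrophic chondrocyte-like cells.

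Osteoprogenitor-like cells of the sorted library differed in 3 genes. Ifi202b, an interferon-inducible gene (ENSMUSG00000026535, chromosome 1), had 0 UMIs in all 3 unsorted libraries and stood at 26.6 CPM in the sorted one (adjusted p = 0.00276). That is at least 96.1-fold higher, counted against 3 UMIs over the unsorted group. Isg15, which encodes an interferon-induced ubiquitin-like protein (chromosome 4), rose from 6.30 ± 2.46 CPM (SD, n = 3) to 38.0 CPM (log2 2.60, SE 0.336, adjusted p = 0.0337). AY036118, an RNA like the ribosomal RNA repeat, fell from 304 to 57.2 CPM (log2 -2.39, adjusted p = 0.0271), and its reads can be shared with ribosomal RNA copies. Eln, which encodes elastin, had a log2 of 1.31 without passing (adjusted p = 0.0849).

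The test ran on 11618 genes, with 826 at an unadjusted p under 0.05, and DESeq2 called 27. The count was 725 without unsorted replicate 1 (396 higher and 329 lower), 61 without replicate 3 and 88 without replicate 4, and 0 with library size in place of TMM factors (730 unadjusted). Genes of G2 and mitosis were higher in 18 of 20 members and 0 over all genes (median log2 0.667, adjusted p = 1.88e-06, 0.803 with an estimated correlation). S phase genes were higher in 18 of 20 and 0 over all genes (adjusted p = 0.0430, 0.827 with an estimated correlation). Immediate-early and heat shock genes were higher in 6 adjusted over the list alone and 0 over all genes (adjusted p = 0.000427, 0.803 with an estimated correlation).

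Hypertrophic chondrocyte-like cells were then set against osteoblast-like cells within each of the 4 libraries, to ask what separates the cell that starts the label from the bone-forming cell. Only some of the osteoblast-like cells held ZsGreen transcripts, and the whole class was used. Genes with the largest differences were named from the pathway lists. Mgp, which encodes an inhibitor of mineralization (ENSMUSG00000030218, chromosome 6), stood at 22600 ± 1620 CPM (SD, n = 4) against 51.5 ± 29.5 (log2 8.17, adjusted p = 0.00379). Tgfb2 was at 353 ± 134 against 6.82 CPM (log2 4.75, adjusted p = 6.5e-06), the BMP antagonist gene Nog at 43.8 ± 4.14 against 0.986 (log2 4.57, adjusted p = 3.52e-10) and the osteoclast-inducing Tnfsf11 at 50.8 ± 25 against 2.86 (log2 3.24, adjusted p = 0.00055). Ctgf, a matricellular growth factor gene, was at 858 ± 214 against 22.6 CPM (log2 4.48), and the glucose transporter gene Slc2a1 at 42.3 against 3.20 CPM (log2 2.92). Among the genes that were lower, Serpinh1, the chaperone of collagen folding, stood at 497 ± 25.3 against 4660 ± 398 CPM (log2 -4.09, adjusted p = 3.98e-12), and Pcolce, which speeds the cutting of the collagen propeptide, at 21.5 against 1070 CPM (log2 -6.48, adjusted p = 0.000131). Creb3l1, a regulator of collagen secretion (log2 -4.73), Mmp2 (log2 -4.64) and the Wnt inhibitor gene Notum (log2 -6.65) were lower as well.

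By edgeR with the library as a block, 9935 of 13595 genes passed, 5052 higher and 4883 lower, and DESeq2 called 9316. These values are relative to the typical gene. Col1a1 alone took 95100 CPM of the osteoblast-like counts of unsorted replicate 1, and scaling by library size alone moved the median gene by log2 0.853, which changed the sign of 1855 of these calls. Each named gene kept its sign. Of the lists the named signals come from, genes of osteoclast regulation were higher in 7 and lower in 1 of 8 (adjusted p = 0.249, 0.829 with an estimated correlation) and those of BMP and TGF-beta signalling higher in 11 and lower in 10 of 23 (adjusted p = 0.938, 0.970 with an estimated correlation), and neither list passed. Genes of type I collagen processing were lower in 19 and higher in 2 of 23 (median log2 -2.31, adjusted p = 4.35e-05, 0.829 with an estimated correlation). Genes of oxidative phosphorylation were lower in 20 of 20 with TMM factors (median log2 -1.27, adjusted p = 2.63e-06, 0.829 with an estimated correlation), and with library size alone 15 were lower and 2 higher. Apoptosis genes were higher in 14 and lower in 3 of 18 with TMM factors (adjusted p = 0.0352, 0.829 with an estimated correlation), and with library size alone the list did not pass (adjusted p = 0.0913). The classes were made by clustering on variable genes and named from marker genes, so differences in such genes are built in. The named genes were taken from outside the markers, but Mgp was among the top 10 genes of the hypertrophic chondrocyte-like cluster. The counts and p-values here and against marrow stromal-like cells thus describe the classes and are not independent evidence.

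The hypertrophic cells were also set against marrow stromal-like cells. Igf1, which encodes the growth factor of the long bones (ENSMUSG00000020053, chromosome 10), stood at 0.603 CPM in hypertrophic chondrocyte-like cells and 936 ± 214 (SD, n = 4) in marrow stromal-like cells (log2 -10.09, adjusted p = 1.1e-10). Il7, which B cell precursors need, was at 0.558 against 114 ± 29.1 CPM (log2 -7.74, adjusted p = 5.58e-16) and Angpt1, a vessel-stabilizing factor gene, at 2.56 against 276 ± 29.1 (log2 -6.51, adjusted p = 4.04e-17). Vegfc (log2 -6.72), Ptn (log2 -6.62) and Sfrp1 (log2 -6.75) were lower too. Higher were Loxl4, which encodes a collagen cross-linking oxidase, at 417 against 2.33 CPM (log2 7.10, adjusted p = 3.66e-18), the osteoprotegerin gene Tnfrsf11b at 77.6 ± 28.1 against 6.22 (log2 3.85, adjusted p = 4.04e-11) and the proapoptotic Bbc3 at 121 against 11.1 (log2 3.34, adjusted p = 5.66e-14). Growth factor genes lay in both directions, with Bmp8a (log2 3.57), Tgfb2 (log2 3.07, adjusted p = 0.000196) and Bmp2 (log2 2.85, adjusted p = 0.00751, lost without unsorted replicate 4 at 0.0574) higher as well.

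In this comparison 7641 of 11928 genes passed, 3943 higher and 3698 lower, and DESeq2 called 6396. Genes of blood cell support were lower in 12 and higher in 1 of 13 (adjusted p = 1.01e-05, 0.266 with an estimated correlation). Genes of BMP and TGF-beta signalling were higher in 10 and lower in 11 of 23 and did not pass (adjusted p = 0.559, 0.669 with an estimated correlation). Genes of G2 and mitosis were lower in 18 of 20 (median log2 -2.41, adjusted p = 1.28e-05, 0.429 with an estimated correlation). Erythroid markers stood at 8030, 7460, 8710 and 6500 CPM in marrow stromal-like cells, where free RNA would give at most 183 CPM, and at 15.6, 575, 119 and 11.8 CPM in hypertrophic chondrocyte-like cells, so transcripts of dividing red cell precursors were not ruled out in that list. Genes of hypoxia and glycolysis were higher in 13 and lower in 1 of 20 (adjusted p = 0.00609, 0.409 with an estimated correlation), and Notch genes were lower in 8 of 11 (adjusted p = 0.00498, 0.368 with an estimated correlation). No list in any comparison of the report passed its threshold with an estimated correlation, where the lowest adjusted p by camera was 0.266. With so few libraries that form of the test could hardly pass, so it cannot decide whether a list moved. In every list past its threshold with the preset correlation, the median, the mean and the test had the same sign.

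The labels of the unsorted samples name endothelial cells for replicates 1 and 2 only. In the single library that stands for both, 27.4% of the cells were endothelial-like (706 of 2581, exact 95% interval 25.6% to 29.1%), as marked by the vascular cadherin gene Cdh5. In replicate 3 no cell was endothelial-like, which allows a share of up to 0.0516%, and in replicate 4 it was 1 cell (0.0173%). B cell-like cells were also most frequent in replicate 1, at 11.8% against 1.87% and 2.03%, and chondrocyte-like cells least frequent, at 3.02% against 22.3% and 26.2%. Replicate 1 thus differed in its mix of cells from replicates 3 and 4, and 1 library on that side left no replicate check. Per the labels' protocols, unsorted cells were depleted with beads against CD31, and the files do not show how far that depletion went in replicate 1.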

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

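The tests of the cluster mix, of free RNA and of Gt(ROSA)26Sor were chosen after the results were seen.

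Immediate-early and heat shock genes, among them Fos, Jun and Egr1, were higher in sorted than in unsorted osteoblast-like cells, with a mean log2 of 1.33 (SE 0.161 over 20 members). The SEs of this paragraph are over list members and do not measure the spread between libraries. With an estimated correlation no list passed in these cells (lowest adjusted p 0.578 by camera). That form of the test could hardly pass with these few libraries. A different mix of the osteoblast-like clusters as the whole cause was argued against by means of 0.507 (SE 0.114) within cluster 10 and 0.774 (SE 0.155) within cluster 11. These lie below 1.33, so part of the difference may come from the mix. Within cluster 10 only 1 gene, Fos, passed over all genes. No list passed there with an estimated correlation (lowest adjusted p 0.904 by camera). Deeper sequencing as the main cause was argued against by cells of 20000 to 40000 UMIs, where the mean was 1.26 (SE 0.162), although a gap in depth was left (medians of 29565, 25716 and 26004.5 UMIs unsorted and 32663.5 sorted). If labelled cells carried more of these transcripts, unsorted cells with a ZsGreen UMI should exceed matched cells without one by about as much as sorted cells exceed unsorted ones, and they exceeded them by a mean log2 of 0.0648 (SE 0.0218). Handling during the sort, the state of the cells, the library and the software version cannot be told apart, since each separates the 1 sorted library from the others, and all stay open.

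Endothelial-like cells of unsorted replicate 1, which no comparison within a class uses, held ZsGreen UMIs in 39 of 706, or 5.52% (exact 95% interval 3.96% to 7.47%, median 13481 UMIs), against 0.987% of B cell-like (6927), 2.55% of erythroid-like (36756) and 3.33% of neutrophil-like cells, and at 10000 UMIs the shares were 3.63% (2.20% to 5.62%), 2.06% (0.251% to 7.25%) in B cell-like and 0.344% in erythroid-like cells, so the contrast with B cells rests on few cells. Their level was 4.02 CPM (2.92 to 5.39) where free RNA would give 0.032 CPM, which argues against free RNA at that estimate. It was 4.80 times that of B cell-like and erythroid-like cells together (2.54 to 9.70). Those cells held 0.838 CPM, also above 0.032 CPM, so the estimate may leave out part of the background. Doublets with 4 skeletal classes were argued against by marker levels, since the cells with a ZsGreen UMI held 1.16% of the hypertrophic chondrocyte, 0.342% of the osteoblast, 1.67% of the marrow stromal and 1.32% of the osteoprogenitor marker level, the last 2 tested after the results were seen. Cre was found in 0 of the 706 cells, which does not exclude earlier expression. Endothelial-like cells were 0 of the 1074 sorted cells. Unsorted replicate 3 also held none and replicate 4 held 1, so this absence cannot decide whether such cells carry the label. No biological explanation was tested.

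Gt(ROSA)26Sor, the noncoding gene at the locus that holds the reporter (chromosome 6, 113067428 to 113077333, minus strand), rose in sorted osteoblast-like cells from 1.01, 1.32 and 0.836 CPM to 6.51 CPM (log2 2.67, SE 0.282, adjusted p = 0.0177 by edgeR), and it was higher without passing in hypertrophic chondrocyte-like (log2 2.97, adjusted p = 0.171), marrow stromal-like (log2 2.21, adjusted p = 0.0523), cluster 12 (log2 2.30, adjusted p = 0.317) and osteoprogenitor-like cells (log2 0.92, adjusted p = 0.759). A larger share of cells with the reporter switched on would raise ZsGreen alike. In osteoblast-like cells ZsGreen had a log2 of 0.65 (SE 0.184), so the rises differed by 2.02 (SE 0.337), which argues against it there. The rises differed by more than 2 standard errors in only 2 of the 4 other groups. In marrow stromal-like cells they differed by 0.728 (SE 0.745), where it stays open. In osteoprogenitor-like cells the difference was -0.795 (SE 0.67), but 64 of the 94 ZsGreen UMIs of the sorted cells lay in 1 cell. That value is not relied on. A batch that unsorted replicate 1 shared with the sorted library was argued against in osteoblast-like cells by its level of 1.01 CPM (0.589 to 1.62), which lay with the other unsorted libraries, but in 1 of the 4 other groups, cluster 12, replicate 1 stood at 4.49 CPM (2.39 to 7.68) against 1.12 and 1.85, so outside osteoblast-like cells it stays open. Biological regulation of the locus was not tested, and the single sorted library and its software version stay open.

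The sorted-unsorted difference itself differed between classes in tests of interaction by edgeR. It differed in 149 genes between osteoblast-like and marrow stromal-like cells, among them Emp1, Igf1 and Dmp1. Igf1 was at 1.07, 0.791, 0.798 and 3.14 CPM in osteoblast-like and 1120, 952, 1040 and 631 CPM in marrow stromal-like cells. Cxcl12 differed too, at 7.55, 15, 15 and 46.2 CPM in osteoblast-like cells. Marrow stromal-like cells were more frequent in the sorted library, so their transcripts are not excluded in osteoblast-like cells for both genes. Between osteoblast-like and hypertrophic chondrocyte-like cells 37 genes differed, among them Emp1 (log2 2.21), Phlda1 (log2 1.85) and Zfp36 (log2 1.83). Between marrow stromal-like and hypertrophic chondrocyte-like cells 87 genes differed, among them Dmp1 (log2 4.79), Mepe (log2 5.87), Cxcl12 (log2 -2.74) and cartilage genes such as Hapln1 (log2 -5.65), Matn3 (log2 -5.86) and Matn1 (log2 -9.38), where free RNA would give 39.4 of the 59.3 CPM of Matn1 in marrow stromal-like cells of unsorted replicate 3, so free RNA of cartilage is not excluded for these. Between osteoblast-like and osteoprogenitor-like cells 62 genes differed, among them Emp1, Sgk1 and Klf6. Transcripts of osteocytes among marrow stromal-like cells were not ruled out for Dmp1 and Mepe. These 4 pairs of classes were chosen after the counts within classes were seen. Of the sorted barcodes left out for over 10% mitochondrial UMIs, 6.79% held a ZsGreen UMI (19 of 280, exact 95% interval 4.13% to 10.4%), above the limit of a count of 0, against 2.93%, 2.58% and 3.62% in the unsorted libraries.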

How the results depend on the processing

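Library size in place of TMM factors, the single osteoblast-like clusters, the range of 20000 to 40000 UMIs and the class comparisons without the sorted library were chosen after the results were seen. No paired analysis was possible because the sorted and unsorted samples share only the number 1. Leaving out unsorted replicate 2 leaves the same library, so it gave no value of its own.

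Counts of genes between sorted and unsorted cells depended on the libraries used. Leaving out each unsorted library gave 0 to 11158 genes over all cells (1519 and 1530 unadjusted for the 0 without replicates 3 and 4), 12 to 672 in hypertrophic chondrocyte-like, 142 to 1297 in marrow stromal-like, 111 to 2896 in osteoblast-like and 61 to 725 in osteoprogenitor-like cells, each highest without replicate 1. Without it, all 229 marrow stromal and all 102 osteoblast calls were shared. Without replicate 3, 92 and 85 were shared, and without replicate 4, 126 and 100. Without replicate 1 the spread comes from 2 libraries that resemble each other, and the sorted library is assumed to vary like them.

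DESeq2 called 2357 genes over all cells and 7, 65, 244 and 27 in hypertrophic chondrocyte-like, marrow stromal-like, osteoblast-like and osteoprogenitor-like cells. Its split differed: 77.9% of the osteoblast calls were higher, against 91.2% by edgeR, 37.6% against 10% over all cells, 42.9% against 100% in hypertrophic chondrocyte-like and 37.0% against 66.7% in osteoprogenitor-like cells. Library size alone left 0 genes over all cells (3404 unadjusted), 0 in hypertrophic chondrocyte-like (577) and 0 in osteoprogenitor-like cells (730), and turned the marrow stromal split from 59.8% to 47.1% higher and that of hypertrophic chondrocyte-like against osteoblast-like cells from 50.9% to 81.2%. With no low-count filter, 77, 352, 296 and 124 genes passed in the 4 classes in the same order. At 2000 UMIs the counts were 9, 6 (4 shared), 64 and 32, where marrow stromal-like cells of replicate 1 were too few to use. Resolution 2.0 gave 177 (3 libraries, 0 shared), 68, 62 and 38, and resolution 0.5 gave 603 in marrow stromal-like (3 libraries), 60 in osteoblast-like and 43 in osteoprogenitor-like cells. Counting the identical libraries as separate gave 1961 genes over all cells, 26 in marrow stromal-like cells, 0 in hypertrophic chondrocyte-like (1243 unadjusted) and 0 in osteoprogenitor-like cells (1410). Over all cells, thinning each cell gave 0 (2070 unadjusted) and leaving out blood classes 0 (1667). Of the osteoblast-like cells, cluster 10 alone gave 1 gene, cluster 11 alone 276 and cells of 20000 to 40000 UMIs 89. The causes of these shifts were not tested.

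Lists past the threshold were 22 over all cells and 9, 8, 11 and 5 within the classes, and 7 and 18 between classes against osteoblast-like and marrow stromal-like cells. With an estimated correlation each of these counts was 0, in a form of the test that could hardly pass with these few libraries. The counts of genes between classes stayed within 1.5 times in every setting.

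Shares of the sorted library depended on how cells were grouped. The osteoblast-like share of 37.0% was 45.8% at a mitochondrial limit of 5%, 42.5% with doublets kept, 41.2% at resolution 0.5, 46.6% at 2.0 and 27.7% with each library clustered alone. The osteoprogenitor-like share of 8.01% was 19.8% at 2000 UMIs, 19.2% and 12.2% at mitochondrial limits of 20% and 5%, 15.9% with doublets kept, and 20.5% and 5.59% at resolutions 0.5 and 2.0. The marrow stromal-like share of 14.8% was 11.1% at 2000 UMIs, 10.8% at both mitochondrial limits, 17.6% with doublets kept, 9.96% and 19.1% at the same resolutions and 9.59% with libraries clustered alone. The hypertrophic chondrocyte-like share of 14.1% was 5.31% at resolution 2.0. At resolution 0.5 and with libraries clustered alone no cluster took that name. The osteocyte-like share of 2.33% was 7.18% at 2000 UMIs and 8.01% with libraries clustered alone, and no cluster took the name at a mitochondrial limit of 5%, with doublets kept or at resolution 2.0. The endothelial-like share of replicate 1 was compared only at 2000 UMIs and at resolution 0.5, and kept within its interval in both.

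Of 1779 values of named genes under other settings, 1463 kept their side of the threshold, 122 lost a call, 189 gained one and 5 changed sign. In hypertrophic chondrocyte-like cells Col1a1 (log2 0.26) and Bglap (log2 1.83) changed sign at 2000 UMIs and Cxcl12 (log2 -0.34) at resolution 2.0, where it also changed sign in marrow stromal-like cells (log2 0.37), and in osteoprogenitor-like cells Eln (log2 -1.15) at resolution 0.5.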

Other observations

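Tests of cells with against without a ZsGreen UMI were planned, and the comparison of labelled shares was chosen after the results were seen.

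A cluster without a name, cluster 12, was marked by Tnc, a matrix gene of forming bone and tendon, and by Cenpf, a kinetochore gene. It was 10.9% of the sorted cells (117 cells, exact 95% interval 9.09% to 12.9%) and 3.73% ± 0.171 (SD, n = 3) of the unsorted ones. In its sorted cells Cxcl1 rose from 5.75 to 34.6 CPM (log2 2.58), Pim1 from 20.6 to 60.2 (log2 1.58), Atf3 from 60.2 ± 1.80 to 164 (log2 1.47) and Isg15 from 1.31 to 18.8 (log2 3.93), each with an adjusted p of 0.0229 by edgeR. These were the 4 genes that passed of 11974, with 1156 without unsorted replicate 1, 0 without replicate 3 (648 unadjusted), 97 without replicate 4 and 31 by DESeq2. With the identical libraries counted as separate, 0 genes passed (1691 unadjusted). A ZsGreen UMI was seen in 18.0%, 17.0%, 19.3% and 29.9% of the cells of cluster 12 (median UMIs 27625.5, 25381.5, 26446 and 44820). At 10000 UMIs per cell the shares were 9.38%, 6.63%, 7.32% and 13.0%, and the ratio of unsorted to sorted, 57.4% (95% interval 30.3% to 115%), includes equal shares.

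Osteoblast-like cluster 11 held more Bglap transcripts in the sorted library. Bglap, which encodes osteocalcin, rose from 2420 ± 451 CPM (SD, n = 3) to 9950 CPM (log2 2.16, SE 0.175, adjusted p = 0.00202) and its neighbour Bglap2 from 658 ± 135 to 4790 CPM (log2 2.97, SE 0.261, adjusted p = 0.0165), although reads of these near-identical copies can be shared. Osteoblast markers were higher in 4 of 12 there (median log2 0.286, adjusted p = 0.0253, 0.471 with an estimated correlation). Cxcl12 rose there from 19.1 to 59.9 CPM (log2 1.72, adjusted p = 0.000618), and Pou3f1, which encodes a POU factor, fell from 80.8 to 13.8 CPM (log2 -2.44, adjusted p = 7.15e-05). Without unsorted replicate 1 the cluster's count went from 276 to 2673 genes.

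Marrow stromal-like cells held hemoglobin transcripts in every library. Hbb-bs, which encodes a beta globin, stood at 5320, 4040, 4710 and 3880 CPM, where free RNA would give 4.94, 88.4, 78.7 and 0.608 CPM. In osteoblast-like cells it stood at 12.2, 163, 75.2 and 3.69 CPM. Ifi202b had 0 UMIs in all cells of the 3 unsorted libraries and 224 in the sorted library, a level of 5.28 CPM that is at least 580-fold higher, counted against 3 UMIs over the unsorted group. In sorted marrow stromal-like cells it stood at 10.3 CPM and in osteoblast-like cells at 0.410 CPM. C57BL/6 mice, the strain of the labels, are known to express little of this gene. The genetic background of the sorted sample was not checked, and a different one would be confounded with the sort. Its relative Ifi204 was at 24.6, 39.2, 48.4 and 37.0 CPM in osteoprogenitor-like cells. In cluster 2, of low UMI counts and no name, 12 of 5715 genes passed, 604 without unsorted replicate 1.

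Only part of the osteoblast-like cells may carry the label at this age. If only part of the unsorted cells is labelled, a ZsGreen UMI should be rarer in them than in sorted cells. At 10000 UMIs per cell the unsorted share was 60.3% of the sorted one in osteoblast-like cells (7.67% against 12.7%, 95% interval of the ratio 43.6% to 84.7%) and 38.1% in marrow stromal-like cells (18.4% to 74.3%). By library the marrow stromal-like ratio was 34.3% (3.98% to 134%), 21.6% (4.23% to 68.7%) and 55.7% (22.2% to 123%), so 2 of the 3 libraries include equal shares, while in osteoblast-like cells it was 53.9% (33.8% to 85.1%), 57.8% (39.5% to 85.3%) and 66.4% (45.7% to 97.3%). The intervals for hypertrophic chondrocyte-like (70.8%, 48.1% to 105%) and osteoprogenitor-like cells (71.1%, 32.8% to 176%) include equal shares. The ratio reads as a labelled share only if labelled cells carry the same ZsGreen level before and after the sort, and a sort gate that keeps the brightest cells would lower it. Its intervals cover counting error only, and the sorted side is 1 library. Cluster 11 made up 17.9%, 29.7% and 30.6% of the unsorted osteoblast-like cells and 62.7% of the sorted ones. No ratio was computed for each cluster.

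Labelled osteoblast-like cells may differ from unlabelled ones of the same tissue. A test within the unsorted libraries called 36 genes other than ZsGreen (10523 tested, library as a block). Cells were matched in UMIs within library and cluster. Hoxb2, a homeobox gene of position along the body axis, was at 130 against 86.0 CPM in cells with and without a ZsGreen UMI (log2 0.58, SE 0.0662, adjusted p = 3.06e-11) and the Wnt inhibitor gene Dkk1 at 69.0 against 48.2 CPM (log2 0.54, adjusted p = 9.97e-05), although Dkk1 was higher in only 2 of the 3 libraries and also marked the osteocyte-like cluster. Lower were Postn, a gene of the periosteum, at 18.7 against 33.1 CPM (log2 -0.88, adjusted p = 4.16e-07) and Igfbp5 at 34.0 against 55.1 CPM (log2 -0.65). Counted with ZsGreen, the same test called 278 of 9930 genes in hypertrophic chondrocyte-like cells, where the match in UMIs was looser (medians 29090 and 26594 in replicate 4), 44 of 7123 in osteoprogenitor-like cells and 24 of 9206 in cluster 12. In osteoprogenitor-like cells Lpl, a lipid uptake gene, was at 715 against 198 CPM (log2 1.85, adjusted p = 4.46e-07), Hoxb2 at 95 against 30.1 CPM (log2 1.61, adjusted p = 0.00137) and Postn at 179 against 518 CPM (log2 -1.53). Rgs5, a marker of mural cells, was at 226 against 0 CPM (adjusted p = 3.38e-08) and Lpl is a marker of marrow stroma, so cells of other types could be mixed in. Many labelled cells lack a ZsGreen UMI, so these differences mix labelled cells into both sides. The match within clusters gave the osteoblast-like clusters the same proportion on both sides.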
